A study of Mus musculus with 8 samples.

How the data were processed

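RNA from the gastrocnemius muscle of mice was measured in 8 libraries, 4 with the genotype label WT and 4 with the genotype label T3TG. Per the labels' protocols, total RNA was isolated with a spin column kit, polyA-enriched libraries were made, and they were sequenced as read pairs on a NovaSeq instrument. The tools listed in the submitters' processing notes are HISAT2 2.2.1, HTSeq 0.9.1 and DESeq2 1.34.0, with the mm10 genome build. The gene annotation and the strand setting of the counting are not given in the sources used here. Antisense genes and overlapping genes can therefore share reads, and genes with near-identical copies have uncertain counts.

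The authors deposited 1 table of raw counts per gene symbol, whole numbers with no normalization, with 35976 rows and 1 column per library. Of the rows, 27 carry a calendar date in place of a symbol, as a spreadsheet program makes from some gene names. They hold between 0.0885% and 0.0961% of the counts of a library and were left out of library sizes and tests. The remaining counts sum to between 16.2 and 28.1 M per library. Gene coordinates come from a RefSeq table of the GRCm38.p6 assembly, which is the assembly behind mm10, and are 1-based.

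In T3TG replicates 2 and 3 nearly all counts are even numbers. Among values from 10 to 99, 97.5% and 98.0% were even there, against 50.5% to 52.5% in the other 6 libraries. Values of exactly 1 occurred 8 and 7 times in them and 1112 to 1378 times in the others. Their totals therefore overstate the number of counted fragments. These libraries hold samples of 1 group only, so a comparison within them was not possible, and the comparison within the 6 other libraries (4 WT, T3TG replicates 1 and 4) is given beside the values from all 8. List medians in the 6 libraries cover the members tested in all 8, and those with 1 library left out cover the members tested in that fit. No pair of libraries agreed within sampling noise, so none was treated as 1 library sequenced again. That check cannot show that the libraries come from separate animals.

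From the counts, genes were filtered with filterByExpr, scaled with TMM factors and tested with the quasi-likelihood test of edgeR 4.0.16 (robust dispersion, R 4.3.3) in a model with group as the only term, T3TG minus WT. P-values were adjusted by the Benjamini-Hochberg method over the 14064 genes tested, with a threshold of 0.05. The SE of a log2 fold change is its absolute value divided by the square root of the F statistic. Levels are CPM, counts scaled to library size, with TMM factors. The labels do not state whether each library comes from a separate animal, so the p-values measure the spread between these samples.

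Before the data were examined, 45 gene lists of pathways, complexes and cell type markers were fixed. The 42 lists with at least 5 tested members were tested with camera of limma 3.58.1 on log2 CPM (prior count 2, preset inter-gene correlation 0.01), adjusted over the 42 lists. camera compares a list with all other genes. Each list was also tested with a correlation estimated from its own members, and with fry, which asks if the members move one way on balance. A score per library is the mean log2 CPM of a list's tested members minus the WT mean, and scores were compared by a two-sided exact permutation test, whose smallest p with 4 against 4 libraries is 0.0286.

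The named genes followed a rule fixed at the same time. It takes Sirt3, per direction the 12 genes with the largest change among those past the threshold without overlap of the groups (filled up by the lowest p-values), and 3 leading members and the most abundant member of each called list and of 5 lists chosen in advance. Unnamed gene models, sex-linked genes and genes under 1 CPM were left out of the 12.

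The scripts were tested on simulated counts drawn from the real means and library sizes. Each gene was given the dispersion of the fitted trend, without its own spread around the trend and without any structure of the samples. Of 100 genes changed by 1.5-fold, 49.0% were recovered, and of 100 changed by 2-fold, 87.0%. Of 165 calls among 13920 simulated genes, 15 were false. A simulated list of 40 genes changed by 1.35-fold was called, and 0 of 100 unchanged lists were. The simulated genes were drawn independently of each other, without the correlation that members of real lists can have. The 0 of 100 therefore does not measure the false calls of the list test in these data. Alternatives were other scaling factors, other filters on low counts, the Wald test of DESeq2 1.42.0, voom with sample weights, a block on the first number in the sample titles, other thresholds, and leaving out each library. After the data were seen, halved counts for the libraries with even values, their removal, a model term for them, and a model term for first title number 6 were added.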

Results

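Gastrocnemius muscle, the large muscle of the calf, was profiled by polyA RNA sequencing in aged mice that had received transplants of blood-forming stem cells. According to the series' design text, the transplanted cells were either control cells or cells that overexpress SIRT3, a deacetylase of mitochondria. The labels name the groups WT (n = 4) and T3TG (n = 4), read here as the control and the SIRT3 arm. Library totals were 18.0, 16.9, 16.2 and 21.5 M counts in WT replicates 1 to 4. In T3TG replicates 1 to 4 they were 20.1, 16.8, 28.1 and 16.9 M counts, and in T3TG replicates 2 and 3 nearly all counts are even numbers. The question addressed is whether the genotype of the transplanted stem cells goes with a difference in the muscle of the recipient.

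Sirt3 itself was measured first, on chromosome 7 from 140863663 to 140882309 (mm10). Its level in the muscle was 18.9 ± 2.49 CPM in WT and 17.7 ± 2.50 CPM in T3TG (SD, n = 4 each). The log2 fold change was -0.09 (SE 0.13), with an adjusted p of 0.881 by the edgeR quasi-likelihood test, and a two-sided exact permutation test over the 8 libraries gave p = 0.486. The 95% interval ran from -0.41 to 0.22, which leaves room for a T3TG level between 0.755 and 1.16 times that of WT. In the 6 libraries without T3TG replicates 2 and 3 the log2 fold change was -0.13.

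Genes of the extracellular matrix led the comparison of T3TG with WT muscle. Fn1, which encodes fibronectin, rose from 44.4 ± 5.89 to 80.8 ± 13.7 CPM, and Col3a1, a chain of fibrillar collagen, from 91.7 ± 14.6 to 148 ± 12.5 CPM (SD, n = 4 each). Their log2 fold changes were 0.87 (SE 0.12) and 0.69 (SE 0.11). Fbn1 (fibrillin), Nid1 (a basement membrane linker), Ltbp4 (a protein that binds latent TGF-beta) and Serpinh1 (the collagen chaperone HSP47) rose by log2 fold changes of 0.53, 0.52, 0.47 and 0.55, with SE between 0.08 and 0.09. Mme, the surface peptidase neprilysin, rose from 6.54 ± 1.01 to 12.5 ± 1.74 CPM, the largest log2 fold change among the called genes at 0.93 (SE 0.16). Pi16, a marker of a fibroblast subset, Thbd (thrombomodulin) and Myadm rose by 0.59, 0.71 and 0.59 on the log2 scale, with SE of 0.10, 0.11 and 0.10.

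These 10 genes were all that passed, out of 14064 tested with the edgeR quasi-likelihood test and Benjamini-Hochberg adjustment, and 0 genes passed in the other direction. Their adjusted p lay between 0.0409 and 0.0462, just under the threshold, and in each of the 10 every T3TG library stood above every WT library. At an unadjusted p under 0.05 there were 827 genes with a higher and 345 with a lower level in T3TG. DESeq2's Wald test called 85 genes higher and 6 lower, among them all 10. In the 6 libraries without the even-count T3TG replicates 2 and 3, the edgeR test called 0 genes (776 at an unadjusted p under 0.05), while the 10 kept a positive log2 fold change of 0.49 to 0.75 and an unadjusted p under 0.05. With no overlap of the groups in the 10, that sign was fixed by their choice. The 6 libraries are part of the data that chose them, so this p is not independent support. The first number in the sample titles, whose meaning is not given, is 6 in 3 T3TG libraries and 1 WT library. With a model term for that number 1 of the 10 passed with edgeR (Col3a1, adjusted p = 0.0479), with log2 fold changes of the 10 from 0.45 to 0.82, and with a block on all title numbers 2 passed (Col3a1 and Fn1). With 1 library left out, 0 of the 10 passed without WT replicate 1, WT replicate 2, T3TG replicate 2 or T3TG replicate 4, and 1, 3, 3 and 8 passed without WT replicate 4, WT replicate 3, T3TG replicate 3 and T3TG replicate 1.

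**Figure D1:**
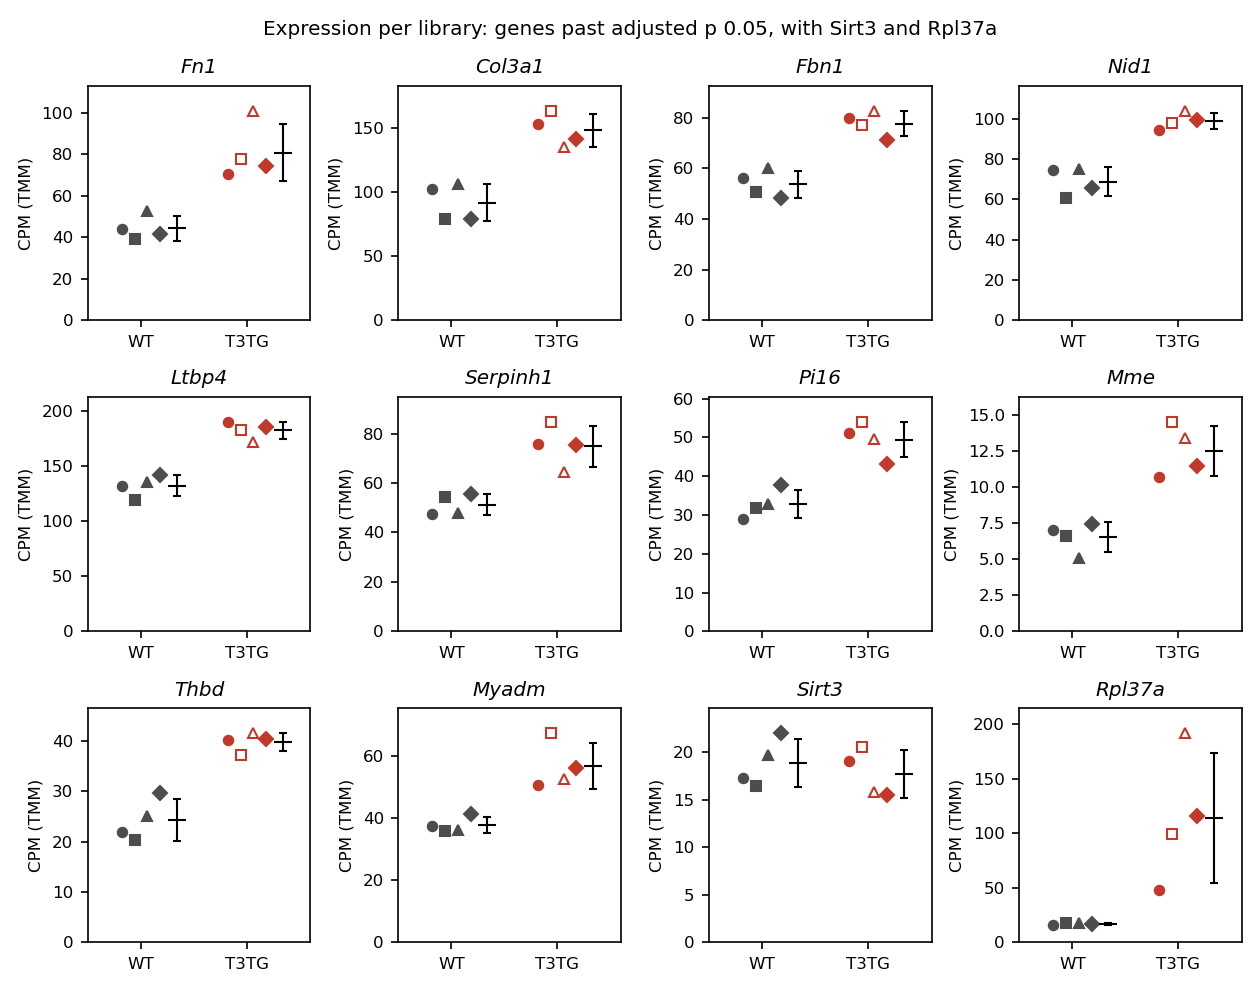
CPM after TMM scaling (y axis, from 0) per library for the 10 genes past the threshold and for Sirt3 and Rpl37a, by group (x axis); each symbol shape is 1 replicate, open symbols are T3TG replicates 2 and 3 with nearly all even counts, and the bar gives the mean and SD (n = 4). The 4 T3TG libraries lie above the 4 WT libraries in every panel except Sirt3, where the groups overlap; Rpl37a did not pass the adjusted threshold.

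The fixed list of matrix and fibrosis genes described the same difference at the level of a group. Of its 43 tested members 40 were higher in T3TG and 3 lower, with a median log2 fold change of 0.43. Of them 5 passed over all genes (Fn1, Col3a1, Nid1, Fbn1 and Serpinh1) and 26 passed adjusted over the list alone. The list was called by camera (adjusted p = 7.59e-30), but at adjusted p = 0.0582 with an estimated correlation it was not. Dcn, the small proteoglycan decorin and the most abundant member, had 473 ± 51.0 CPM in WT and 625 ± 99.8 CPM in T3TG and did not pass over all genes (log2 fold change 0.40, SE 0.11, edgeR adjusted p = 0.257). Prelp, another matrix proteoglycan, and the proprotein convertase Pcsk6 came closest to the threshold from outside, with log2 fold changes of 0.49 (SE 0.09) and 0.55 (SE 0.10) and an edgeR adjusted p of 0.0629 for both. DESeq2 called both (adjusted p = 0.00156 for each).

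Markers of fibro-adipogenic progenitors, the mesenchymal cells between the fibers, were higher in T3TG in all 23 tested members, with a median log2 fold change of 0.44. This list shares 7 tested members with the matrix list. Of its members 4 passed over all genes (Col3a1, Fbn1, Mme and Pi16) and 18 adjusted over the list alone, among them Gsn with 881 ± 104 CPM in WT and 1153 ± 111 CPM in T3TG. The camera call (adjusted p = 5.27e-24) was at adjusted p = 0.0811 with an estimated correlation. In the 6 libraries the medians of the same members were 0.44 for the matrix list and 0.30 for the progenitor list. The scores of both lists separated the groups in all 8 libraries (two-sided exact permutation p = 0.0286, the smallest possible). Markers of smooth muscle and pericytes (median 0.08, camera adjusted p = 0.0794), Schwann cells (0.09, 0.0869) and tenocytes (0.18, 0.191) were not called.

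Macrophage markers had higher values in T3TG in 22 of 23 tested members (median log2 fold change 0.54). With edgeR 0 passed over all genes (14 at an unadjusted p under 0.05) and 11 adjusted over the list alone, and with DESeq2 Mrc1 alone passed over all genes (adjusted p = 0.00280). Mrc1, the mannose receptor of tissue macrophages, had a log2 fold change of 0.60 (SE 0.11, edgeR adjusted p = 0.0696). Csf1r, the receptor for macrophage colony-stimulating factor, had 19.3 ± 1.93 CPM in WT and 27.9 ± 5.91 CPM in T3TG, and Cd68, a lysosomal glycoprotein, 0.83 (SE 0.22) on the log2 scale. Complement genes, 3 of them also on the macrophage list, were higher in 17 of 19 (median 0.57). None passed over all genes with edgeR or DESeq2 (12 at an unadjusted edgeR p under 0.05), and 4 passed adjusted over the list alone, among them C1ra and Cfb, with log2 fold changes of 0.68 and 0.85, and Cfp, which was named after its value was seen (0.62). The camera calls of these lists (adjusted p = 2.68e-13 and 2.32e-09) were both at adjusted p = 0.306 with an estimated correlation. The medians were 0.28 and 0.26 in the 6 libraries, without T3TG replicate 3 alone they were 0.333 for both, and T3TG replicate 3 had the highest scores, 0.94 for macrophage markers against 0.27 to 0.43 in the other T3TG libraries.

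Antigen presentation genes (median log2 fold change 0.27, 20 of 24 higher) and interferon-stimulated genes (0.21, 34 of 42 higher) were also called by camera, with adjusted p of 7.44e-05 and 1.78e-04. With an estimated correlation the adjusted p was 0.508 for both, and by the edgeR test 0 members passed over all genes or adjusted over the list alone, with 3 and 5 members higher and 0 and 1 lower at an unadjusted p under 0.05. Ifi27l2a, induced by interferon, had a log2 fold change of 1.41 (SE 0.35, edgeR adjusted p = 0.273). Bst2 and Rsad2, both antiviral effectors, had log2 fold changes of 0.53 (SE 0.15) and 0.99 (SE 0.31), and Tapbp, which loads peptides on MHC molecules, 0.22 (SE 0.08). DESeq2 called Ifi27l2a (adjusted p = 0.00147) and no other member of these lists. The medians in the 6 libraries were 0.16 for antigen presentation and 0.12 for the interferon list, which was not called there (camera adjusted p = 0.0668). Leaving out 1 library moved the first median to 0.433 (WT replicate 2), 0.174 (WT replicate 3) and 0.157 (T3TG replicate 3), and the second to 0.337 (WT replicate 2), 0.111 (WT replicate 4) and 0.117 (T3TG replicate 3).

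Inflammatory cytokines and NF-kB targets had a median log2 fold change of 0.28 in 21 tested members (camera adjusted p = 0.0181, adjusted p = 0.503 with an estimated correlation). With edgeR and with DESeq2 0 passed over all genes (5 at an unadjusted edgeR p under 0.05), and 3 passed adjusted over the list alone: the chemokine genes Ccl2 (1.80, SE 0.48) and Cxcl14 (0.35, SE 0.11) and the alarmin gene Il33 (0.53, SE 0.15). Its median was 0.11 in the 6 libraries, where it was not called (camera adjusted p = 0.164), and its call was lost without WT replicate 4, T3TG replicate 1 or T3TG replicate 3 and with the stricter filter on low counts (camera adjusted p = 0.0557). Its median was 0.142 without WT replicate 2 and 0.0679 without T3TG replicate 3. Senescence-associated genes, 2 of them also on the matrix list, were higher in 19 of 23 tested members (median 0.21, camera adjusted p = 8.27e-05, adjusted p = 0.0761 with an estimated correlation), with scores that separated the groups. With edgeR 0 of these passed over all genes (8 higher and 1 lower at an unadjusted p under 0.05), with DESeq2 Igfbp4 and Igfbp7 did (adjusted p = 0.0145 and 0.0469), and 4 passed adjusted over the list alone: Igfbp4 and Igfbp7, secreted binding proteins of insulin-like growth factors (0.49, SE 0.11, and 0.38, SE 0.09), Ccl2, and Timp2, an inhibitor of matrix proteases named after its value was seen (0.30, SE 0.09).

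Endothelial markers were higher in 21 of 22 tested members (median log2 fold change 0.26, camera adjusted p = 1.37e-07, adjusted p = 0.306 with an estimated correlation). None passed over all genes by the edgeR test, 7 had an unadjusted p under 0.05, DESeq2 called Eng (adjusted p = 0.00312), and 2 passed adjusted over the list alone: Eng (endoglin), at 59.5 ± 7.06 CPM in WT and 82.5 ± 4.42 CPM in T3TG, and Tie1, a receptor kinase of vessels (0.40, SE 0.10). The endothelial median was 0.16 in the 6 libraries, 0.164 without WT replicate 2 and 0.174 without T3TG replicate 3 alone. Adipocyte markers had a median of 0.44 in 23 tested members with a wide interquartile range, 0.05 to 1.53 (camera adjusted p = 1.92e-06, adjusted p = 0.340 with an estimated correlation), and 0 passed adjusted over the list alone. Their scores were 0.75, 0.40 and 1.26 in T3TG replicates 2, 3 and 4, and -0.11 in T3TG replicate 1. Scd1, a fatty acid desaturase, had 41.1 ± 10.6 CPM in WT and 129 ± 80.1 CPM in T3TG, and Cebpa, a transcription factor of fat cells, had a log2 fold change of 0.63 (SE 0.21). Bone and cartilage markers (median 0.29, 6 of 6 higher, camera adjusted p = 0.0353, adjusted p = 0.306 with an estimated correlation) held 1 member that passed adjusted over the list alone, Acp5, a phosphatase of osteoclasts and macrophages (1.85, SE 0.41), and the call was lost in the 6 libraries (camera adjusted p = 0.0668) and without WT replicate 1, WT replicate 2, T3TG replicate 3 or T3TG replicate 4. Over all genes Acp5 passed with DESeq2 (adjusted p = 0.0143) and not with edgeR (adjusted p = 0.112).

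**Figure D2:**
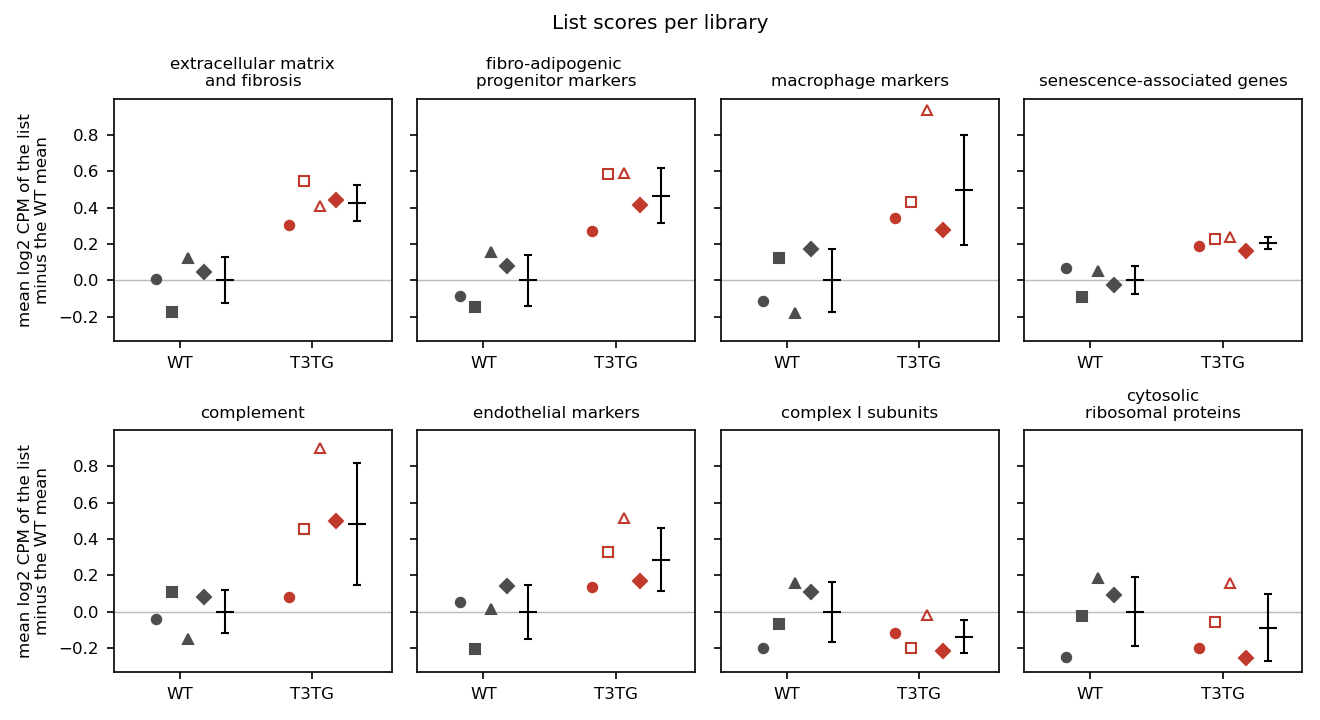
Mean log2 CPM of a list's tested genes minus the WT mean (y axis) per library by group (x axis) for 8 called lists; each symbol shape is 1 replicate, open symbols are T3TG replicates 2 and 3 with nearly all even counts, and the bar gives the mean and SD (n = 4). The matrix, progenitor, macrophage and senescence scores of all T3TG libraries lie above those of all WT libraries, and in the other 4 panels the groups overlap.

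Genes of mitochondrial respiration, mitochondrial ribosomes and the proteasome had slightly lower values in T3TG in nearly all members. All 36 tested subunits of complex I were lower, with a median log2 fold change of -0.13, a median difference of -8.82%. Ndufa3 and Ndufs4, for example, had -0.31 (SE 0.11) and -0.20 (SE 0.09). Subunits of complexes II to V were lower in 40 of 41 (median -0.12, with Cox8b at -0.34, SE 0.12, and Uqcr10 at -0.21, SE 0.10), mitochondrial ribosomal proteins in 69 of 76 (-0.11, with Mrps28 at -0.30, SE 0.09) and proteasome subunits in 31 of 31 (-0.08, with Psmd8 at -0.24, SE 0.10). In these 4 lists 0 members passed by the edgeR test, over all genes or adjusted over the list alone, and 4, 1, 5 and 1 members were lower at an unadjusted p under 0.05. The camera calls (adjusted p = 4.02e-08, 3.69e-07, 1.37e-07 and 1.78e-04) were all at adjusted p = 0.508 with an estimated correlation, and the WT libraries alone spanned complex I scores from -0.20 to 0.16. In the 6 libraries the medians were -0.19, -0.16, -0.14 and -0.11, and without WT replicate 3 they shrank to -0.0756, -0.0745, -0.0745 and -0.0482. Complex I was at -0.205 without WT replicate 1, and the proteasome at -0.0519 without T3TG replicate 4.

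Cytosolic ribosomal protein genes were lower in 73 of 76 tested members (median log2 fold change -0.11, and -0.25 in the 6 libraries), with Rps21 at -0.45 (SE 0.16). Without WT replicate 3 or T3TG replicate 4 the median was -0.0638 and -0.0679, and without WT replicate 1 or T3TG replicate 3 it was -0.198 and -0.207. The camera call (adjusted p = 3.26e-07) was at adjusted p = 0.592 with an estimated correlation. Rpl37a moved against its group and was the only member past 0.05 adjusted over the list alone. It had 17.2 ± 0.858 CPM in WT and 114 ± 59.5 CPM in T3TG, with no overlap of the groups (log2 fold change 2.73, SE 0.42). It did not pass over all genes with edgeR (adjusted p = 0.123) and did with DESeq2 (adjusted p = 6.80e-08), and in the 6 libraries its log2 fold change was 2.26. Rpl37a lies on chromosome 1 from 72711260 to 72713813 (mm10) and has a processed pseudogene in the annotation, so reads may have been split between copies.

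Fatty acid oxidation genes (median log2 fold change -0.08, 23 of 30 lower), tricarboxylic acid cycle genes (-0.06, 23 of 24 lower) and fast fiber genes (-0.11, 18 of 20 lower) were called lower with camera adjusted p of 0.00204, 0.00819 and 0.0104. With an estimated correlation the adjusted p was 0.592, 0.585 and 0.585, and by the edgeR test 0 members passed over all genes or over the list alone, with 2, 0 and 1 lower at an unadjusted p under 0.05. Plin5, a lipid droplet protein, had -0.35 (SE 0.14) and Fabp3, a fatty acid carrier, -0.29 (SE 0.14). Mpc1, the pyruvate carrier, had -0.15 (SE 0.08). Pvalb, the calcium buffer of fast fibers, had 8754 ± 1180 CPM in WT and 7505 ± 453 CPM in T3TG, and Tmod4 -0.18 (SE 0.09), whereas Myh4, the main fast myosin, had 30221 ± 3469 and 31253 ± 6649 CPM (0.05, SE 0.14). The fatty acid list lost its call without WT replicate 4 (median -0.0404; -0.152 without WT replicate 2), the cycle list without WT replicate 4 (-0.0244) or T3TG replicate 2 and in the 6 libraries (camera adjusted p = 0.0642), and the fiber list without T3TG replicate 1 (-0.0628) or 2. Circadian clock genes were called at the edge of the threshold (median -0.10, camera adjusted p = 0.0480, adjusted p = 0.306 with an estimated correlation), with Ciart lower (-0.70, SE 0.21) and Npas2 higher (0.54, SE 0.23), neither past the edgeR threshold, and the call was lost in the 6 libraries (camera adjusted p = 0.126) and in 6 of the 8 fits that leave out 1 library, kept only without WT replicate 4 or T3TG replicate 4. The stricter filter on low counts also ended it (camera adjusted p = 0.0527), and its median was -0.0634 without T3TG replicate 2.

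**Figure D3:**
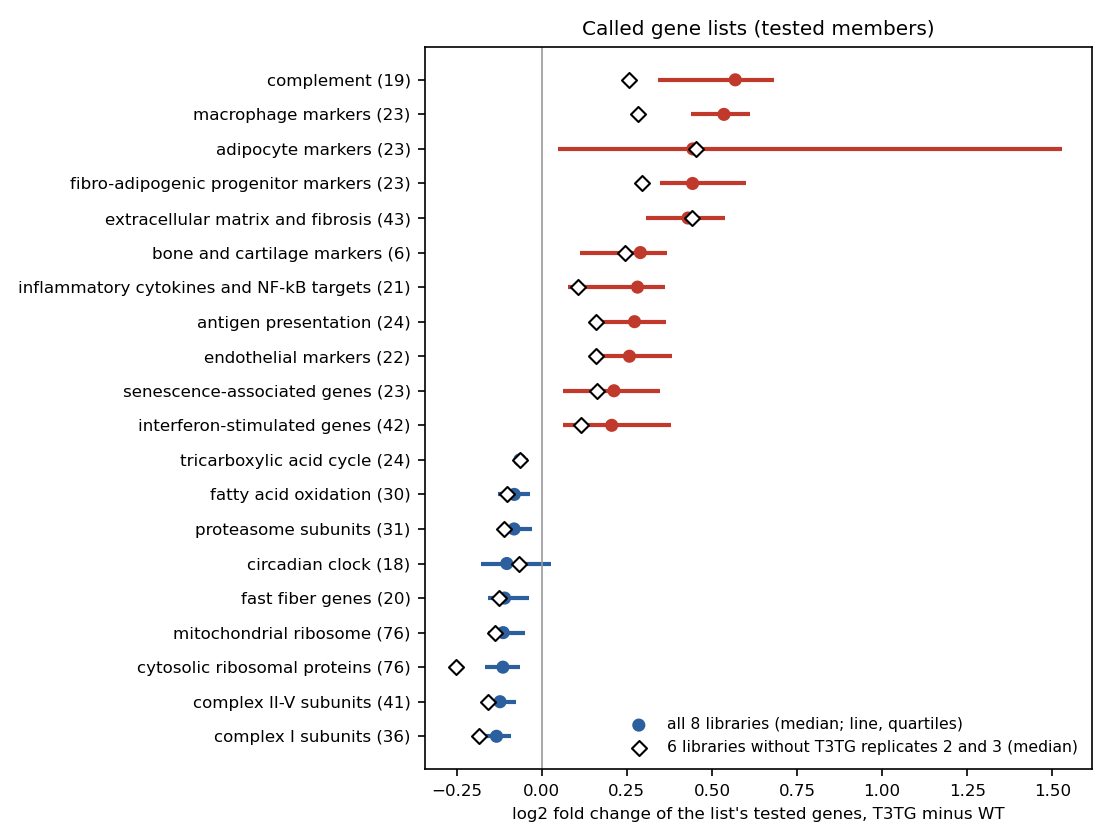
Log2 fold change, T3TG minus WT (x axis), of the 20 gene lists called by camera with the preset correlation (y axis, number of tested members in brackets); filled points are medians over genes from all 8 libraries, lines the quartiles over genes, and open diamonds medians from the 6 libraries without T3TG replicates 2 and 3. Of the 20 lists, 11 lie to the right of 0 and 9 to the left, and the medians from the 6 libraries lie on the same side.

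In all, camera called 20 of the 42 lists with the preset correlation, 11 higher and 9 lower, and 0 with an estimated correlation. The smallest adjusted p with an estimated correlation was 0.0582, and 5 lists had an unadjusted p under 0.05. By fry, 3 lists passed, those of matrix, progenitor and senescence genes (adjusted p = 0.0171, 0.0382 and 0.0467). The matrix list shares 7 members with the progenitor list and 2 with the senescence list. Of the 20 lists 15 were called in the same direction in the 6 libraries. Of the 1015 distinct genes in these tests 7 passed over all genes with edgeR and 31 with DESeq2.

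Muscle programs that did not differ by these tests included the atrophy program, with a median log2 fold change of 0.00 in 28 tested members (camera adjusted p = 0.937). Its members Fst (follistatin) and Foxo4 had 0.51 (SE 0.19) and -0.24 (SE 0.09), neither past the edgeR threshold. For slow fiber genes (-0.14, 0.305) the missing call does not show equal levels, since the median was as low as that of the called fast fiber list (-0.11). The WT libraries differed widely in some members, with Tnnt1 at 424 CPM in WT replicate 4 and 132 to 184 CPM in the other WT libraries. Slow fiber genes, glycolysis and glycogen genes (-0.01, 0.794), satellite cell markers (-0.00, 0.211), denervation and regenerating fiber genes (0.09, 0.580), neuromuscular junction genes (0.06, 0.563) and insulin and IGF signaling genes (0.01, 0.871) were not called, each given with its median and its camera adjusted p. The same holds for mitochondrially encoded genes (-0.09, 0.238), sirtuins and mitochondrial biogenesis (-0.06, 0.121), antioxidant genes (-0.02, 0.219), autophagy and mitophagy (-0.01, 0.160), heat shock and unfolded protein response (0.10, 0.0596) and lipid and cholesterol synthesis (-0.00, 0.219). Immediate early genes (0.08, 0.405), p53 targets (-0.01, 0.350), cell cycle genes (0.05, 0.830), neutrophil and monocyte markers (0.20, 0.937), erythroid and platelet markers (0.91, 0.136) and sex-linked genes (-0.13, 0.0630) were not called either. The medians of neutrophil and monocyte and of erythroid and platelet markers were -0.46 and -0.27 in the 6 libraries, and T3TG replicate 3 had the highest scores of both, 1.39 and 1.81. The test's direction was opposite to the median for the atrophy, cell cycle, satellite cell and lipid synthesis lists. Among mitochondrially encoded genes, COX1 had 37318 CPM in WT. COX2, COX3, ATP6, ND3 and ND4L had only 65.0, 26.7, 18.2, 11.6 and 2.93 CPM there. That list's median thus rests in part on genes with few counts. Markers of T and NK cells, of B and plasma cells and of skin had 4 tested members each and were not tested, with median log2 fold changes of 0.07, 0.19 and -0.10.

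No gene with a lower level in T3TG passed the adjusted threshold with edgeR in the model with group alone, after the filter on low counts, in all 8 libraries. Rpl37rt passed it without WT replicate 3 (log2 fold change -1.36, adjusted p = 0.0270), with a block on the title numbers (-1.54, adjusted p = 0.0105) and with a term for title number 6 (-1.44, adjusted p = 0.0479), and 3 genes passed it without the filter. The 12 lowest unadjusted p-values in that direction belonged to Ppargc1b, Junos, Rpl37rt, Usp40, Ciapin1, Upf3b, Kcnf1, Cdk2ap1, Ciart, Ankrd23, Gtf2h5 and Pstk, with log2 fold changes from -1.16 to -0.29. Ppargc1b, a coactivator of mitochondrial biogenesis, had 25.9 ± 3.72 CPM in WT and 16.8 ± 2.72 CPM in T3TG (log2 fold change -0.63, SE 0.13, edgeR adjusted p = 0.109) and passed adjusted over the list of sirtuins and mitochondrial biogenesis alone (adjusted p = 0.00694). Kcnf1, a potassium channel subunit, had -0.83 (SE 0.21), and Ankrd23, a titin-binding muscle protein, 3244 ± 148 CPM in WT and 2645 ± 162 CPM in T3TG (-0.29, SE 0.09). Junos is transcribed opposite to Jun and Rpl37rt is a retrocopy of Rpl37, so both values can hold reads of their partners. DESeq2 called 5 of the 12: Rpl37rt, Kcnf1, Ppargc1b, Ankrd23 and Junos.

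By rank alone, 439 genes had all 4 T3TG libraries above all 4 WT libraries and 233 had them below. Together these were 672 of the 14064 tested genes, 4.78%, where chance gives 2.86%, or 402 genes. Among the 10 called genes all were of the first kind. In the 6 libraries the count was 2049 of 14507, 14.1%, where chance gives 13.3% for 4 against 2 libraries.

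The libraries of the groups did not form separate clusters. The first principal component of the 1000 most variable genes held 24.9% of the variance, with WT replicates 1 to 4 at -11.6, -11.2, -13.8 and 1.97 and T3TG replicates 1 to 4 at -7.09, 13.1, 22.0 and 6.78. WT replicate 4 and T3TG replicate 1 thus lay on the side of the other group, and the 4 libraries with first title number 6 (WT replicate 4 and T3TG replicates 2, 3 and 4) lay apart from the others. Pairwise correlations of log2 CPM ran from 0.972 to 0.985.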

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

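The tests on the libraries with even counts, on first title number 6, on the share of muscle fibers, on dilution of fiber transcripts, on a general rise of ribosomal protein genes and on shared copies were chosen only after the results were seen. In each group of 4 libraries, a library far from the other 3 was looked for in 188 sets of values, and 5 held one, 2.66%, where chance gives about 5%. These were a bone and cartilage score of 0.31 in WT replicate 3 (others -0.13 to -0.06), 18296 detected genes in the same library (others 18720 to 18753), and a TMM factor of 0.988 in WT replicate 1 (others 0.981). The other 2 were a position of 1.97 on the first principal component in WT replicate 4 (others -13.8 to -11.2) and, in CPM without TMM factors, 450 CPM of globin transcripts in T3TG replicate 3 (others 62.5 to 74.7). The check cannot find 2 libraries that deviate together, so the even counts of T3TG replicates 2 and 3 are not among the 5. The 2.66% therefore does not show that the libraries of a group are alike.

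Chance cannot be excluded as the source of the counts of called genes and lists. Of the 35 splits of the 8 libraries into 4 and 4, 3 gave at least the 10 genes of the real split, the real one included, and the highest other gave 106. That split sets WT replicates 1, 2 and 3 and T3TG replicate 1 against the rest, as the first principal component orders the libraries, and it is exactly the split by first title number, 6 against 1, 2 and 3. It points to a structure of the samples that goes with that number and is partly confounded with the genotype label, since 3 T3TG libraries and 1 WT library carry the number 6. For called lists the real count was 20, with 3 splits as large and 20 as the highest other. The median of the other splits was 15 called lists, so most of such a count arises without the real grouping. For list members past the threshold it was 7, with 3 splits as large and 17 as the highest other. For genes without overlap of the groups it was 672, with 3 splits as large and 805 as the highest other, so the excess over 2.86% does not exclude chance either.

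The higher matrix list in T3TG was weighed against 4 explanations. The even-count libraries as its whole source are argued against by the 6 other libraries, where the list's median log2 fold change was 0.44. A difference that goes with first title number 6 as its whole source is argued against by the median of 0.41 with a model term for that number, although the term leaves 1 of the 10 genes past the threshold. That argument is weak. WT replicate 4 is the only WT library with the number 6, and T3TG replicate 1 is the only T3TG library with another number. A lower share of muscle fibers would raise all other cell types alike, and the progenitor score rose above the smooth muscle and pericyte score by 0.37. In this difference all 4 T3TG libraries lay above all 4 WT libraries (exact permutation p = 0.0286). It cannot decide the question, since the smooth muscle list is not free of fiber transcripts, with Des at 3705 CPM in WT. In that list Des and Lmod1 fell (log2 fold changes -0.11 and -0.30), while Acta2 and Myh11 rose (0.43 and 0.42). A lower share of fibers therefore stays open. More progenitor cells with an unchanged matrix program stay open, since no difference between matrix and progenitor genes, shared members left out, was resolved (-0.036, exact permutation p = 0.629). The genotype of the transplanted cells may contribute, as may chance, with 0.44 measured in only 2 T3TG libraries with ordinary counts.

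The lower complex I list in T3TG cannot be told apart from a dilution of fiber transcripts by RNA of other cells. Its difference from the score of fast fiber genes did not separate the groups (-0.035, exact permutation p = 0.800), and the SD of that difference was 0.189 in WT.

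Rpl37a stood against its group, and 3 explanations were weighed. A general rise of ribosomal protein genes is argued against by their median of -0.12. A genomic interval in which many genes differ between the groups is argued against by the 23 tested genes within 2 Mb, whose median absolute z of 0.777 lay at percentile 48.5 of 10000 random sets. A median cannot show an interval that changes only a few genes, and 1 of the 23 is Fn1, itself among the 10 called genes. That narrower case stays open. Reads shared with a near-identical copy stay open: in WT, Rpl37a lay at 7.49% of the median of the other ribosomal protein genes, so most of its reads may be lost to copies, and the 1 annotated pseudogene has no entry in the table. A difference in the reads lost and a biological difference between the groups were not separated.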

How the results depend on the processing

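The alternatives that halve the counts of T3TG replicates 2 and 3, leave both out, add a model term for them or add a term for first title number 6 were chosen after seeing the data. The number of genes past the threshold, 10, was also 10 under the other scaling factors, the stricter filter and halved counts, and 9 with voom. It was 107 without a filter on low counts, where the median prior degrees of freedom rose from 9.50 to 103. It was 4 with a block on the first title number, of which Col3a1 and Fn1 are among the 10 and the others are Fstl1 and the lower Rpl37rt (adjusted p of the 10, 0.0111 to 0.616). It was 2 with the term for title number 6, Col3a1 and the lower Rpl37rt (adjusted p of the 10, 0.0479 to 0.210). It was 91 with DESeq2, 30 at an adjusted p of 0.10 and 0 at a log2 fold change of at least 1. It was 0 by edgeR both in the 6 libraries and with the even-count term (776 and 699 genes at an unadjusted p under 0.05). Leaving out 1 library gave 0 (without WT replicate 1, WT replicate 2, T3TG replicate 2 or T3TG replicate 4) to 37 (without T3TG replicate 1), and 5, 1 and 3 without WT replicate 3, WT replicate 4 and T3TG replicate 3. Changed list members, 7, were 30 without a filter, 2 with the block, 1 with the term for number 6, 31 with DESeq2, 0 in the 6 libraries and with the even-count term, and 0 to 15 with 1 library left out. The lists called, 20, were 0 with an estimated correlation, 3 by fry, and 19 to 25 otherwise. The stricter filter ended the calls of the inflammatory and circadian lists. With the block 24 lists were called and with the term for number 6 there were 23, and in each fit only 18 of the 20 kept their call. Genes with no overlap, 672, were 2049 in the 6 libraries and 1028 to 1371 with 1 library left out, since fewer libraries overlap less by chance (13.3% and 5.71% against 2.86%). Apart from the filter and the no-overlap counts, the cause was not tested. In all 19 alternative fits the 10 genes kept a positive log2 fold change and an unadjusted p under 0.05. No called list reversed in the fits that gave list calls. The 10 genes were chosen and the lists were called in these same libraries, so their sign and p in these fits are not independent support. Of the named genes only Myh4 reversed: from 0.05 to -0.01 without WT replicate 3, -0.10 without T3TG replicate 4 and -0.021 with the block, and it was 0.12 without T3TG replicate 2. Named genes gave 1069 values on the same side of the threshold, 103 weaker and 40 stronger, and called lists 309 and 71 weaker. Deviations from the group means of libraries sharing a title number correlated at -0.05 to 0.15; as 3 of the 4 T3TG libraries share number 6, this does not measure a difference between number 6 and the others. Pseudocounts and filters on normalized values do not apply to counts, DESeq2 and voom give no list calls, and the block and the terms no count without overlap. At these library sizes and sample numbers, with the spread of the dispersion trend, 49.0% of simulated 1.5-fold changes were recovered. The spread of single genes around that trend and the structure of the samples were left out, so the real share may be lower. Depth itself was not varied, so its share in this limit was not tested.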

Other observations

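Mast cell markers were tested as a list added after the data were seen. Of its 14 members 8 were tested. Of these 7 were higher in T3TG, 6 of them at an unadjusted p under 0.05, with a median log2 fold change of 0.88 (0.53 in the 6 libraries without T3TG replicates 2 and 3). By camera the unadjusted p was 2.06e-07, and 0.00458 with an estimated correlation. Since the list was added with these data already seen, these p-values are not independent support. Cpa3, a carboxypeptidase of mast cell granules, had 2.69 ± 0.238 CPM in WT and 7.03 ± 2.88 CPM in T3TG (edgeR adjusted p = 0.0696), and Mcpt4, a chymase, had a log2 fold change of 0.89 (SE 0.19). With DESeq2, Cpa3, Mcpt4 and a further member, Cma1, passed over all genes (adjusted p = 0.00156, 0.00885 and 0.0498).

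G6pdx, an antioxidant list member named after its value was seen, had a log2 fold change of 0.91 and passed adjusted over its list alone (adjusted p = 0.0169, edgeR). Over all genes G6pdx passed with DESeq2 (adjusted p = 0.0214) and not with edgeR (adjusted p = 0.123). Eif2s3y, on the Y chromosome and also named afterwards, had -0.37 and passed adjusted over the sex-linked list alone (adjusted p = 0.0279, edgeR). Xist was at 3.47 to 6.70 CPM and Ddx3y at 67.7 to 86.4 CPM in all 8 libraries.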
